A study of Mus musculus with 18 samples.

How the data were processed

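The series holds 18 libraries of the immunoglobulin heavy chain locus around the JH4 segment, amplified from genomic DNA of mouse splenic germinal center B cells sorted 14 days after immunization with the hapten conjugate NP-CGG. Sample titles place 7 libraries in the WT group, 7 in the KO group and 4 in the AIDKO group. Group assignment used the titles. The genotype label of WT replicates 5 to 7 is the one that KO replicates 1 to 4 carry, a floxed Ldha allele with Cre at the Aicda locus, so the assignment of those 3 libraries rests on the title alone, and values of set A, which holds replicates 1 to 4, are given beside the pooled differences in intron frequency, in frequency over all analysed positions and in the authors' averages. A letter in the sample descriptions divides the libraries into set A (WT and KO replicates 1 to 4, AIDKO replicates 1 and 2) and set B (WT and KO replicates 5 to 7, AIDKO replicates 3 and 4). The labels do not state whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Ldha itself is outside the amplicon and its loss could not be checked here. The AIDKO libraries, labelled with Cre on both Aicda alleles and so without the deaminase that starts hypermutation, gave the background.

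Per the labels' protocols, amplicons were made by reverse complement PCR with the primers CATAACAAAGGTTAAAAATAAAGAC and GCCTGACATCTGAGGACTC, without molecular identifiers being mentioned, and sequenced as paired-end reads. GATK 4.1.9.0 and R 4.2.1 are named per the submitters' processing notes. The aligner, the handling of duplicate reads and any read filter are not given in the sources used here. The deposited file of each library lists, for each position of a custom reference contig, the reference base, the string of bases read and the string of base qualities, a unit other than a count or a normalized value. The authors' deposited table gives for each library the fraction of mismatching bases at 39 positions from 1100 to 1139, with position 1108 left out, and an average. Of those positions, 10 lie in the forward primer and 29 past it. All fractions of the 18 libraries in the authors' table equalled the share of mismatching bases of quality 30 or more in the base strings within 1e-12, and the average equalled the share pooled over positions. Without a quality minimum the largest difference was 1.36 percentage points. All columns of the table belong to these libraries.

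Positions are those of the authors' contig, which runs from 968 to 1310. No genome was used here, so no chromosome coordinates are printed. The sequence is the antisense strand of the immunoglobulin coding strand, and bases are given as read on it. The forward PCR primer covers 1086 to 1110 and the reverse primer 1223 to 1241, which makes an amplicon of 156 bp. The splice donor placed the intron up to 1129 and the JH4 exon, 54 bp long in the gene table of GRCm38.p6, from 1130 to 1183. The stretch of intron between primer and exon is 19 positions long.

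Bases of quality 30 or more were counted in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Primer positions were left out, as were positions with fewer than 100 bases in any library, with a mismatch share of 20% or more in any library, or with a mean share of 1% or more over the AIDKO libraries. This left 57 positions, 19 in the intron, 28 in the exon and 10 past it. Past the exon, AIDKO means of single positions ran from 0.396 to 2.77 mismatches per 1000 bases, against 0.369 over the intron. What sequence lies there was not determined, so mismatches past the exon cannot be taken as hypermutation alone. A share of 20% or more removed 44 positions, the first being 1079, 1080 and 1081 outside the amplicon, with highest shares of 99.8%, 100% and 98.7%, and the AIDKO mean removed 27. Overall mutation frequency was the number of mismatching bases per 1000 bases over the intron positions. Motif classes, substitutions, windows of 50 positions and single positions used all 57 positions. Groups were compared by two-sided exact permutation of group labels within set A and within set B, with 95% intervals by inverting the test where the number of splits allowed one. Differences were taken within each set and averaged with weights from the group sizes. P-values were adjusted by the Benjamini-Hochberg method within each family. Single positions were tested with limma 3.58.1 in R 4.3.3 on log2((mismatches + 0.5)/(matches + 0.5)), all 18 libraries in one fit with set as a term, and an adjusted p below 0.05 was called. Position log2 changes are on that scale and understate changes at low frequencies. Single libraries are given with 95% Wilson intervals, and these cover counting error only, since PCR reads are not independent molecules.

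The position rule, set before the data were examined, named the 10 positions with the highest WT frequency after subtracting AIDKO among those called for WT against AIDKO (6 were called), up to 10 called positions for KO against WT or, with fewer than 3 called, the 5 with the smallest p, and up to 3 positions removed for a share of 20% or more. Motif classes were fixed at the same time as the G and C of AGCT, other WRC/GYW sites, SYC/GRS sites, WA/TW sites and the rest, with 12 substitutions and 4 background-subtracted shares. The order of bases in the strings allowed reads to be followed from 1114 to 1202, where all positions of a library have the same number of bases. Deletions lay next to deletions in 87.4% to 90.7% of cases, against 24.3% to 43.6% after shuffling. Clonotypes were distinct sequences from 1171 to 1202, a stretch that sequencing errors and hypermutation can split. Between 84.6% and 99.5% of sequences seen 2 to 20 times had an even count, a sign that both mates of a pair were counted and that intervals are too narrow.

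Alternatives tried were base quality minimums of 0 and 20, a depth minimum of 1000, no limits and stricter limits on mismatch shares, primer positions kept, each library left out, each set alone, no set term, a replicate block, WT replicates 5 to 7 moved or left out, a minimum base share of 0.1%, a median over positions, a log2 scale, a pseudocount of 5, motif classes without order, windows of 100 positions and a common AIDKO background. Added after the data were seen were all analysed positions, the authors' positions past the primer, exon positions, intron positions where reads can be followed, each clonotype of 10 or more reads weighted equally, reads with a linked mismatch pattern left out, and, over all analysed positions and for clonotypes, each library left out and each set alone. No pair of libraries in a group agreed within sampling noise, the lowest chi-square per position being 10.6. On simulated data with the WT spread in both groups (SD of the natural log 0.533), the permutation test of KO against WT called 3.7% of 1000 simulations without a change, 56.7% with KO at 0.5 of WT and 99.0% with KO at 0.25 of WT. On the log scale KO libraries spread more widely (SD of the natural log 1.32). This includes KO replicate 4 at 0.118 mismatches per 1000 intron bases, while the other KO libraries had 1.42 to 5.70. On the plain scale the SD was 1.90 in KO and 2.02 in WT. With each group's own log SD and the ratio of means kept, the test called 17.1%, 53.1% and 81.6%, so with spreads that unequal it calls more than 5% without a change in the mean. The limma fit of KO against WT, tested on 2000 simulated positions, recovered 0%, 2.99% and 22.7% of positions changed by 1, 2 and 4 on the log2 scale.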

Results

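Somatic hypermutation was measured as mismatches to the reference in JH4 amplicons of splenic germinal center B cells, the B cells that mutate their antibody genes after immunization. Libraries titled WT (7) were set against libraries titled KO (7), in a series on cells with and without lactate dehydrogenase A (LDHA), an enzyme of glycolysis. WT replicates 5 to 7 carry the floxed genotype label of KO replicates 1 to 4, so that these 3 libraries held LDHA-sufficient cells rests on their titles. AIDKO cells (4 libraries) lack activation-induced cytidine deaminase, the enzyme that starts hypermutation. Depth reached 4306 to 12306 reads in WT, 8082 to 12345 in KO and 8609 to 13430 in AIDKO libraries. The intron frequency rested on 81492 to 254390 bases per library.

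The JH4 intron carried 3.11 ± 2.02 mismatches per 1000 bases in WT (SD, n = 7), 2.95 ± 1.90 in KO (SD, n = 7) and 0.369 ± 0.263 in AIDKO (SD, n = 4). Means in WT and KO were 8.43 and 8.01 times the AIDKO mean. All 7 WT libraries and 6 of 7 KO libraries lay above the highest AIDKO library, and KO replicate 4 lay within the AIDKO range with 0.118 mismatches per 1000 bases (95% Wilson interval 0.0773 to 0.181). WT replicate 2 had the highest frequency, 7.44 per 1000 bases (95% Wilson interval 7.05 to 7.85).

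**Figure D1:**
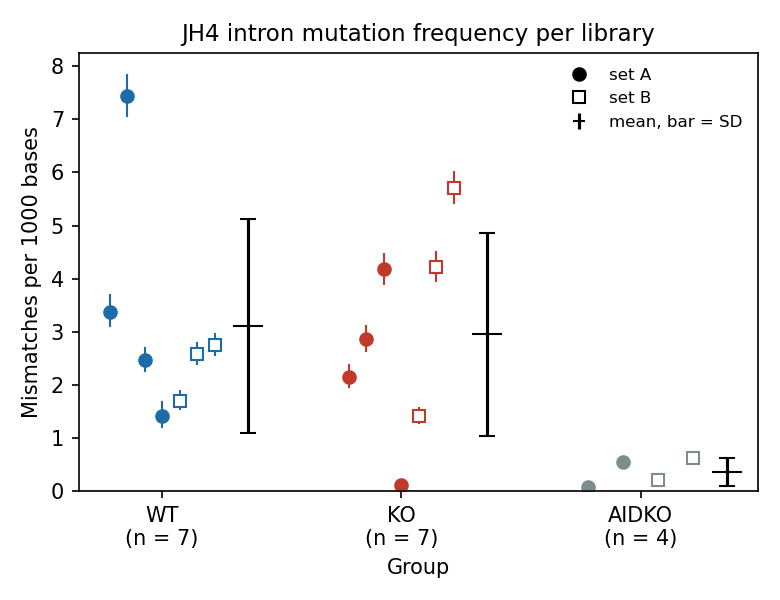
Mismatches per 1000 bases at the 19 JH4 intron positions of each library, by group. Points are libraries with 95% Wilson intervals, filled circles set A and open squares set B, and black marks are the mean and SD of the group. WT and KO libraries overlap, with means of 3.11 and 2.95, and KO replicate 4 sits at 0.118 among the AIDKO libraries.

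The question of the series, whether LDHA-deficient cells hypermutate differently, was addressed by KO against WT. The difference, KO minus WT, was -0.157 per 1000 bases (95% interval -2.70 to 2.12, exact permutation p = 0.893, 1400 splits), smaller than the spread between replicates. The interval allows changes of most of the WT mean in either direction. In set A, where titles and genotype labels do not conflict, the difference was -1.35 (95% interval -7.32 to 2.75, exact permutation p = 0.486), and in set B it was 1.43 (exact permutation p = 0.4, the smallest p possible there being 0.1). The difference between the sets, -2.78, did not pass an exact permutation test (p = 0.209). It was -1.53 without WT replicate 2, -1.82 without KO replicate 7, -1.47 with primer positions kept and 0.197 over all analysed positions. Leaving out WT replicate 2, KO replicate 4 or KO replicate 5 turned the sign, to 0.618, 0.342 and 0.136, and over all 57 analysed positions KO minus WT was 0.740 (exact permutation p = 0.52), with 0.824 in set A and 0.627 in set B, and -0.0699 without KO replicate 1.

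WT libraries exceeded AIDKO libraries by 2.68 per 1000 bases (95% interval 0.618 to 5.44, exact permutation p = 0.0333, 150 splits), and KO libraries exceeded them by 2.65 (95% interval 0.181 to 5.08, exact permutation p = 0.0333). Both are within-set differences averaged over the sets, and the plain differences of means were 2.74 for WT and 2.58 for KO. Neither set alone could reach a p below 0.05 for these comparisons. The excess per 1000 bases was 3.36 in set A and 1.93 in set B for WT, and 2.01 and 3.36 for KO. Both calls ended when any 1 of the 4 AIDKO libraries was left out (exact permutation p from 0.05 to 0.08), and the KO call also without KO replicate 2, 3, 6 or 7 (exact permutation p from 0.05 to 0.06). Over all 57 analysed positions the KO excess was 2.56 (exact permutation p = 0.0533), with 2.84 in set A and 2.25 in set B. Without a limit on mismatch shares, 7 positions outside the amplicon entered, and the excess was 9.10 for WT and 7.44 for KO.

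The authors' deposited table averages 1.77 mismatches per 1000 bases over the WT libraries, 1.67 over KO and 0.391 over AIDKO. That table includes primer and exon positions beside the intron. On the authors' averages, KO minus WT was -0.0984 per 1000 bases (95% interval -1.40 to 1.04, exact permutation p = 0.867), with -0.758 in set A and 0.781 in set B. WT exceeded AIDKO by 1.35 (exact permutation p = 0.0133) and KO by 1.32 (exact permutation p = 0.0467) in the authors' averages. In set A these were 1.81 and 1.05, and in set B 0.839 and 1.62, where neither set alone could reach a p below 0.05. The WT call ended without AIDKO replicate 1, 2 or 3 (exact permutation p from 0.05 to 0.1). The KO call ended without any single AIDKO or KO library other than KO replicate 4 (exact permutation p from 0.0556 to 0.133). KO minus WT turned to 0.291, 0.173 and 0.0679 without WT replicate 2, KO replicate 4 and KO replicate 5. Over the 14 WT and KO libraries the authors' averages followed the intron frequency (Pearson r = 0.987, Spearman rho = 0.925, permutation p = 1e-05 for each, the smallest 100000 resamples give). Without WT replicate 2 and KO replicate 7, Pearson r was 0.960. Both measures are computed from shared bases, so they are not independent.

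At single positions, limma called in WT 6 of 57 positions above AIDKO (10 at an unadjusted p below 0.05), 3 in the intron and 3 in the exon, and none below. Positions with a mean share of 1% or more in AIDKO had been left out, which favours calls above AIDKO over calls below it. Position 1123, a T in a WA/TW site (a motif favoured by DNA polymerase eta), had the highest WT frequency above background, with 22.2 ± 9.50 mismatches per 1000 bases (SD, n = 7) against 0.190 ± 0.179 in AIDKO (SD, n = 4). Its log2 change was 6.93 (SE 1.11, limma adjusted p = 0.000122). KO had 22.5 ± 15.1 there (SD, n = 7), and 6 of 7 KO libraries exceeded every AIDKO library. Position 1164 in the exon, a G in a WRC/GYW hotspot of the deaminase, had 13.5 ± 8.77 in WT and 12.1 ± 7.19 in KO, above every AIDKO library in 6 of 7 libraries of each group. Position 1155, a T in a WA/TW site of the exon, had 11.6 ± 12.6 in WT and 13.1 ± 6.03 in KO. Positions 1126, 1125 and 1150 had 7.35 ± 9.08, 6.58 ± 9.34 and 2.54 ± 1.39 in WT, with 4.45 ± 8.62, 7.27 ± 6.61 and 1.61 ± 1.81 in KO. Single libraries carried part of these means. Without WT replicate 2 the WT mean was 4.02 at 1126 and 3.13 at 1125, without KO replicate 7 the KO mean at 1126 was 1.27, and without WT replicate 3 the WT mean at 1155 was 7.10. For these 5 positions the log2 change of WT over AIDKO was 3.81 to 6.19 (limma adjusted p from 0.00711 to 0.0443).

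**Figure D2:**
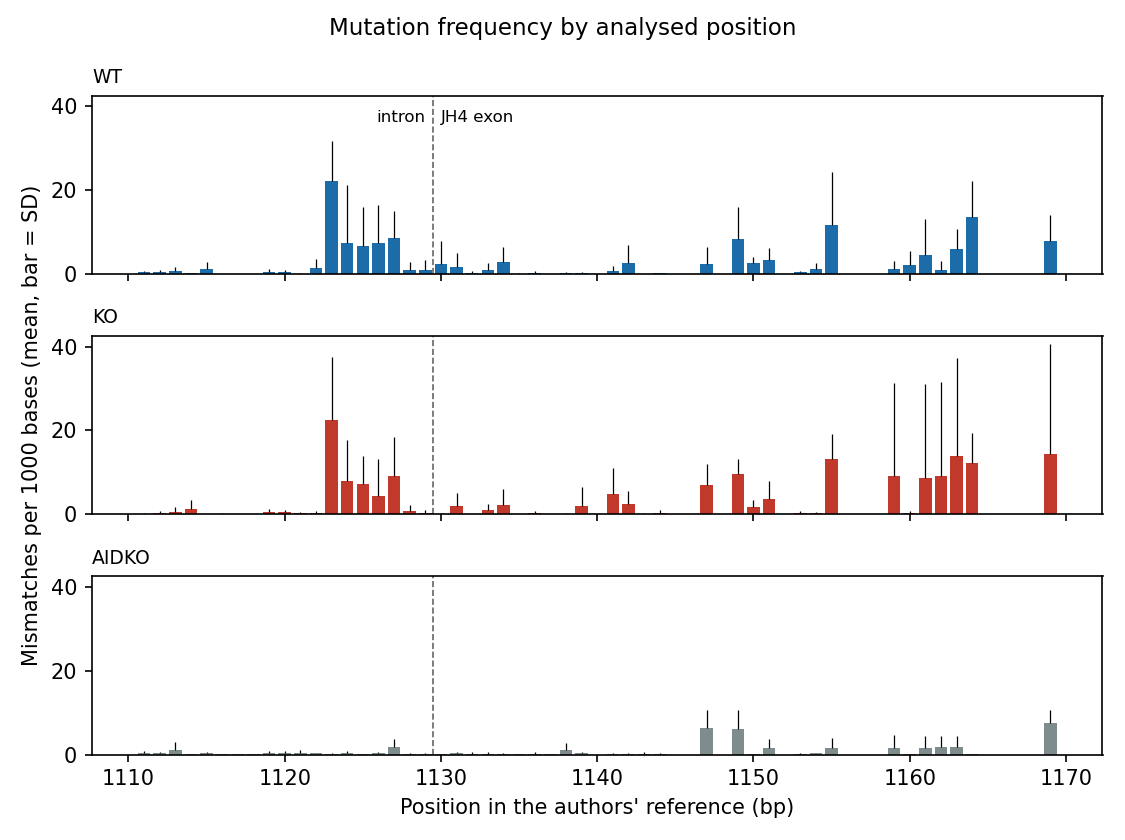
Mean mismatches per 1000 bases at each analysed position up to 1169 of the authors' reference, for WT, KO and AIDKO libraries, with upward bars for the SD and a dashed line at the start of the JH4 exon. Position 1123 stands highest in the intron in WT and KO, at 22.2 and 22.5, with 0.190 in AIDKO.

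Against AIDKO, limma called 4 positions in KO, namely 1123, 1164, 1155 and 1125, all higher. Their log2 changes were 6.29, 5.93, 4.30 and 4.89, with adjusted p from 0.000493 to 0.0433. WT and KO share the same AIDKO libraries, so overlap between their lists is not independent evidence. Leaving out AIDKO replicate 3 reduced the WT count to 1 and the KO count to 1, and leaving out AIDKO replicate 1 reduced the KO count to 1. Without AIDKO replicate 2, or without KO replicate 2, 5, 6 or 7, the KO count was 2.

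Between KO and WT limma called 0 of 57 positions, with 5 at an unadjusted p below 0.05. These 5, none past the threshold, were 1147, 1141, 1115, 1126 and 1160. Position 1147 had 7.05 ± 4.86 mismatches per 1000 bases in KO (SD, n = 7) and 2.43 ± 4.02 in WT (SD, n = 7), a log2 change of 3.73 (SE 1.10, limma adjusted p = 0.146), but AIDKO libraries also had 6.24 ± 4.48 (SD, n = 4). Without WT replicate 5 the WT mean was 1.01, and without AIDKO replicate 2 the AIDKO mean was 4.12. This position was called in set A alone, with a log2 change of 7.13 (limma adjusted p = 0.00033), with WT replicates 5 to 7 moved to KO or left out, with 6.87 and 6.84, and without WT replicate 5, with 4.42 (limma adjusted p = 0.0249). Apart from the last, these settings all used the same WT libraries, so their calls are not independent. With reads that carry a linked exon pattern left out, the log2 change at 1147 was 0.76 (limma adjusted p = 0.875). Over its 32 alternatives the limma adjusted p ran from 4.44e-06 to 0.984. Log2 changes at 1141, 1115, 1126 and 1160 were 3.05, -2.61, -2.26 and -2.47, each with a limma adjusted p of 0.422.

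By sequence motif, WA/TW sites (9 positions) carried the most mismatches in WT and KO, 7.44 ± 2.71 and 7.62 ± 4.12 per 1000 bases, with 1.41 ± 1.10 in AIDKO. WRC/GYW hotspots (4 positions) had 4.75 ± 2.01 in WT, 3.69 ± 2.31 in KO and 0.193 ± 0.297 in AIDKO. There AIDKO replicate 4 had 0.634 and the other AIDKO libraries 0 to 0.100. In SYC/GRS coldspots of the deaminase (13 positions), WT had 1.32 ± 1.01 and AIDKO 1.57 ± 0.258, while KO had 3.29 ± 5.58, with KO replicate 1 at 15.9. Position 1147 of this class, in the exon stretch of the linked mismatch patterns, had 6.24 per 1000 bases in AIDKO. KO minus WT in this class was 1.97, and -0.125 without KO replicate 1. Other positions (31) had 1.95 ± 1.32, 2.57 ± 2.08 and 0.831 ± 0.190, and KO minus WT there turned from 0.616 to -0.154 without KO replicate 1. No AGCT site passed the position filters. KO minus WT went opposite ways in sets A and B at WA/TW sites (-2.54 and 3.81) and SYC/GRS sites (3.81 and -0.466), and was -1.37 and -0.642 at WRC/GYW sites and 0.828 and 0.333 at other positions. None of the 4 classes passed the threshold for KO against WT by exact permutation, adjusted or unadjusted (lowest adjusted p = 0.798).

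In the substitution spectrum, T-to-C changes were the most frequent per reference base in WT and KO, 3.84 ± 1.55 and 4.36 ± 2.49 per 1000 T, with 0.479 ± 0.399 in AIDKO. KO minus WT for T-to-C was -0.846 in set A and 2.34 in set B. G-to-A changes had 1.5 ± 0.748 in WT, 2.08 ± 0.750 in KO and 0.825 ± 0.53 in AIDKO. Of the 17 G positions, 1141, 1143, 1147, 1149 and 1150 lie in the exon stretch of the linked mismatch patterns. With all substitutions counted, 1147 and 1149 had 2.43 and 8.34 per 1000 bases in WT, 7.05 and 9.53 in KO and 6.24 and 6.11 in AIDKO. The AIDKO means at 1141, 1143 and 1150 were lower, 0.149, 0.226 and 0.0746. Of 12 substitutions 0 passed the adjusted threshold and 1 had an unadjusted p below 0.05. This was C-to-A, with 0.653 ± 0.372 in WT, 0.217 ± 0.150 in KO and 0.228 ± 0.187 in AIDKO (exact permutation p = 0.0286, adjusted p = 0.343), and KO minus WT was -0.557 in set A and -0.273 in set B. Without KO replicate 1, KO minus WT turned for C-to-T from 0.910 to -0.0725, for C-to-G from 1.22 to -0.138 and for A-to-G from 0.345 to -0.263. After background subtraction, the mean share of mutations at A:T pairs, KO minus WT, was -25.3 percentage points (exact permutation p = 0.480, adjusted p = 0.640). It was -55.3 in set A, 14.7 in set B, 36.2 with primer positions kept and 308 without AIDKO replicate 1. With reads that carry a linked pattern left out it was 4.76, so its direction depended on these choices. None of the 4 shares passed the threshold by exact permutation (lowest adjusted p = 0.557; 0 at an unadjusted p below 0.05), and shares of single WT and KO libraries ran above 100%, up to 280%, or below 0, which limits their use.

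Along the amplicon, windows spanned 50 positions but held fewer analysed ones. The window that starts past the forward primer (42 analysed positions) had 2.48 ± 1.07 mismatches per 1000 bases in WT, 2.76 ± 1.29 in KO and 0.672 ± 0.313 in AIDKO. The window from 1161 (7 analysed positions) had 5.52 ± 3.69, 9.24 ± 13.4 and 2.53 ± 0.760, with KO replicate 1 at 39.1. Without it, KO minus WT turned from 3.71 to -1.41. The window from 1211 (8 analysed positions) had 2.58 ± 1.17, 3.12 ± 1.34 and 1.71 ± 2.25, with AIDKO replicate 3 at 5.05 and the other AIDKO libraries at 0.337 to 1.05. In sets A and B, KO minus WT was -0.162 and 0.873 in the first window, 7.10 and -0.800 in the window from 1161, and 0.515 and 0.575 in the window from 1211. None of the 3 windows passed the threshold for KO against WT by exact permutation (lowest adjusted p = 0.757), and 0 had an unadjusted p below 0.05.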

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

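The rule for libraries that stand apart was set before the data were examined, and the tests of explanations were chosen after the results had been seen. Of 93 groups of libraries tested for a library far from the others, 33 libraries stood apart, where chance gives about 1 in 20 groups of normally distributed values. For 6 of them every other library of the group was at 0, so that any mismatch stood apart, and many of the measures share bases, so the number is not a count of independent events. KO replicate 1 accounted for 8 of them and WT replicate 2 for 7.

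WT replicate 2 had 7.44 intron mismatches per 1000 bases, above 1.42 to 3.38 in the other WT libraries, and an authors' average of 3.95. It also stood apart at 4.68 in the first window, 3.77 for C-to-T, 5.03 for T-to-G, 27.3 at position 1126 and 27.3 at position 1125. The values at 1126 and 1125 were nearly equal, and whether the same reads carried both was not tested. Weighting each clonotype equally left this library at 8.36 against 3.79 for the next WT library. Errors and hypermutation can split 1 lineage into several clonotypes, so this weighting cannot exclude a few large lineages. Sequencing error spread over all positions is argued against by its median over intron positions, 0.217 per 1000 bases, within the range of the other WT libraries (up to 0.854). A few large lineages remain open, as do a more mutated cell population and a technical enrichment of mutated templates, which were not tested. Each of these may be the source.

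KO replicate 4 had 0.118 intron mismatches per 1000 bases, within the AIDKO range, and stood apart at position 1155 with 0.214, where the other KO libraries had 12.2 to 17.9. Depth is not the limit, since its upper 95% bound of 0.181 lies below 1.42 in the lowest other KO library. A swap with an AIDKO library of set A lacks a partner, since the higher of those had 0.555. Its largest clonotype held 1.83% of reads, below 4.89% in the highest KO library, so a few unmutated clonotypes did not hold most reads. The other KO libraries, 6 of 6, lay above the highest AIDKO library. KO replicate 4 was picked because it did not, so that count cannot decide about loss of LDHA. Loss of LDHA, a single wrong label or a less mutated sample may each be the source, and none of them was tested.

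Linked mismatches between 1140 and 1158 of the JH4 exon formed 3 patterns, found after the data were seen, carried together by 0% to 6.64% of reads in a library. Hypermutation is argued against by AIDKO libraries, whose median share of 2.82% was above 1.34% in WT and KO. Reads joined from 2 templates are a candidate explanation, for example during PCR. Of 285 AIDKO reads with part of a pattern, 97.2% carried it as an unbroken run that reached an end of the pattern. In set A the shares did not overlap, 0% to 0.152% in WT and 1.23% to 3.40% in KO (exact permutation p = 0.0286, the smallest possible), while in set B they did (exact permutation p = 0.7) and over both sets p was 0.369, and the source of a further template was not tested.

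KO replicate 1 stood apart at 39.1 in the window from 1161, 15.9 at SYC/GRS sites, 6.96 at other positions, 4.77 for A-to-G, 9.54 for C-to-G, 8.04 for C-to-T, 3.96 for T-to-G and 18.1 at position 1141, all per 1000 bases. Several of these may rest on 1 stretch. The highest KO values at 1159, 1161, 1162 and 1163 were nearly equal, 59.6, 59.6, 60.0 and 59.7 per 1000 bases. The highest AIDKO values there were also nearly equal, 6.04, 5.81, 5.81 and 5.82. Whether the same reads carried these mismatches was not tested. AIDKO replicate 3 stood apart at 5.05 in the window from 1211, 1.12 for A-to-T and 0.749 for T-to-G. AIDKO replicate 4 stood apart at 0.634 at WRC/GYW sites, 5.23 at position 1155, 0.298 at 1125, 0.298 at 1150 and 0.224 at 1160. Single values apart from their group were 0.00879 for G-to-C in AIDKO replicate 2, 0.71 for G-to-C in KO replicate 2, 1.10 for G-to-T and 10.9 at position 1147 in WT replicate 5, 38.8 at position 1155 in WT replicate 3, 3.13 at position 1141 in WT replicate 1, 23.5 at position 1126 and 0.162 at position 1115 in KO replicate 7, and 1.35 at position 1160 in KO replicate 6. Among 44 primer positions, left out of the intron frequency, position 1099 was first noticed by eye, not by the rule. A scan made afterwards found 1 position where all 6 WT and KO libraries of set B lay above every AIDKO library. It was position 1099, with a mean of 97.0 mismatches per 1000 bases in those 6 against at most 59.1 in AIDKO. How often chance gives such a position among 44 was not tested.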

How the results depend on the processing

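Alternatives on the positions used, on clonotypes and on linked reads were chosen after the data were seen, and the cause of each change below was not tested unless given. The counts of alternatives include some that cannot change a comparison, such as leaving out a library of neither group, motif order or window size. These repeat the main value, so the counts overstate how widely each result was tried. Moving WT replicates 5 to 7 to KO or leaving them out left no WT library in set B, so permutation then repeated set A alone. The KO minus WT difference in intron frequency stayed short of the threshold in all 42 alternatives (p from 0.331 to 1). Its sign turned with primer positions kept (0.00158), in set B only (1.43), over all analysed positions (0.740) and over exon positions (1.44), and it ranged from -0.667 to 0.618 with 1 library left out. The last pair rests on KO replicate 1, with -0.0699 and -0.303 without it, and ranges with 1 library left out of -0.0699 to 1.17 and -0.303 to 2.09. With no position left out for its share, 7 positions outside the amplicon entered, and KO minus WT was -1.79, WT above AIDKO 9.10 and KO above AIDKO 7.44. The difference between sets turned over all analysed positions (0.197) and exon positions (1.86), was -0.340 with a median over positions, and ranged from -3.97 to -1.53 with 1 library left out. WT above AIDKO kept its direction in all 40 alternatives and passed the threshold in 30. It missed it without a quality minimum (2.20), with primer positions kept (1.01), in set A only and with WT replicates 5 to 7 left out (3.36 in both), in set B only (1.93), where too few splits exist, and with a median over positions (0.225), and it ranged from 2.02 to 3.02 with 1 library left out. Over exon positions it was 1.57. KO above AIDKO passed in 26 of 40, and missed it with primer positions kept (1.08), in set A only (2.01), in set B only (3.36), with a median over positions (0.0914), over all analysed positions (2.56) and over exon positions (2.92), ranging from 2.18 to 3.10 with 1 library left out. On the authors' averages, set A only gave 1.81 for WT and 1.05 for KO above AIDKO, and set B only 0.839 and 1.62, all short of the threshold. KO minus WT there was 0.781 in set B only, and leaving out 1 library gave -0.368 to 0.291 for KO minus WT, 1.02 to 1.55 for WT and 1.08 to 1.58 for KO above AIDKO.

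Positions called for KO against WT, 0 in the main setting, were 1 in set A only, with WT replicates 5 to 7 left out and with those moved to KO, in each case position 1147, and 0 to 1 with 1 library left out. For WT against AIDKO, 6 became 3 in the authors' window, 3 with no position left out for its share, 11 with primer positions kept, 1 in set A only and 3 in set B only, and 1 to 7 with 1 library left out. For KO against AIDKO, 4 became 2 in the authors' window, 1 without a quality minimum, 1 with no position left out for its share, 2 without a set term, 15 with primer positions kept and 0 in set A only, and 1 to 5 with 1 library left out. Fewer positions or libraries enter the window and the single sets. Log2 changes turned at 1126 for KO against AIDKO in set A only (-0.39), and at 1147 (-0.80) and 1126 (0.74) for KO against WT in set B only. Among 951 values of single classes, shares and windows, none of them called, 109 changed sign, and some of the 951 came from alternatives that cannot change them. Of 100 splits of the libraries, the real one included, 1 gave as many positions as WT against AIDKO (6, highest other 5). For KO against AIDKO 2 gave as many (4, highest other 4), so another split equalled the real one. These splits cannot exclude chance. The positions had been filtered by their mean in the real AIDKO libraries, which favours the real grouping, and the splits crossed the sets. All 100 gave at least the 0 of KO against WT (highest other 2), which a count of 0 makes certain, so these splits say nothing about it. With a replicate block, KO minus WT was -0.157 (sign-flip exact p = 0.953) and 0 positions were called. Replicate numbers gave no clear pairing of the libraries, as correlations of same-numbered WT and KO libraries ran from -0.444 to 0.199. Of 7 WT libraries 3 correlated best with their own number, replicates 1, 2 and 4, all of set A. No chance level was computed, and mismatch values cannot exclude a shared origin of same-numbered libraries. A planned count model per position was left out, so its calls are not known. A depth minimum of 1000 changed no value.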

Other observations

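All tests in this part were chosen after the values had been seen. Reads with at least 1 mismatch in the part of the intron where reads can be followed made up 5.29% ± 3.46 of WT (SD, n = 7), 5.33% ± 3.36 of KO (SD, n = 7) and 0.509% ± 0.358 of AIDKO reads (SD, n = 4), so most reads carried no intron mismatch. Clonotypes of 10 or more reads numbered 91 to 479 in WT, 90 to 457 in KO and 156 to 319 in AIDKO libraries, and the largest clonotype held 1.78% to 7.04% of reads.

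Loss of LDHA was examined as a hypothesis for clonal diversity. The effective number of clonotypes of 10 or more reads, KO minus WT, was 12.8 (95% interval -71.8 to 102, exact permutation p = 0.767), and over all sequences -88.4 (exact permutation p = 0.283), which leaves the hypothesis open, since a p above the threshold does not show that diversity was alike. Over all sequences the difference was 10.5 in set A (exact permutation p = 0.743) and -220.2 in set B (exact permutation p = 0.3), the set whose WT labels conflict. It was -33.6, -57.0 and -52.8 without WT replicate 5, KO replicate 6 and KO replicate 7. Among clonotypes of 10 or more reads it was 14.3 in set A and 10.9 in set B, and turned to -15.2 and -7.65 without WT replicate 5 and KO replicate 5. Set B libraries had 135 more effective clonotypes of 10 or more reads than set A libraries (exact permutation p = 0.00068), and 348 more over all sequences (exact permutation p = 0.000272). More reads in set B may be the reason. With every library thinned to 4306 reads, set B stayed higher by 307 over all sequences (exact permutation p = 0.000272), which argues against read number as the whole cause there. Among clonotypes of 10 or more reads the difference was then -14.2 (exact permutation p = 0.269), but with fewer reads a fixed minimum leaves out more clonotypes of a more diverse library, so depth and set cannot be told apart for these.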
